A study of Lactiplantibacillus plantarum with 16 samples.

How the data were processed

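Gene expression was measured with spotted two-colour arrays on which 1 RNA was labelled with Cy3 and the other with Cy5. Per the labels' protocols, cells were quenched in cold methanol buffer, RNA was isolated after bead beating, and amino allyl cDNA primed with random nonamers was coupled to the dyes. Per the file headers, the deposited scanner tables were made with ImaGene and hold, for each of the 6912 spots of an array, the brightness (intensity) of the spot and of its surroundings in both channels, with no background subtraction. Channel 1 is Cyanine 3 and channel 2 Cyanine 5. The software also set flags and a mark for empty spots, and their thresholds are not given in the sources used here. The authors' value table holds log2 ratios with unstated scale, centring and direction. Compared with the scanner values, its entries equalled the log2 ratio of the mean intensities minus the mean background to within 0.016 in every spot where both could be computed, with no centring (array medians from -2.06 to 2.28). Its direction was Cy5 over Cy3 in the 8 arrays of culture R and Cy3 over Cy5 in the 8 arrays of culture L, and why it was chosen stays unknown.

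The genotype, stage and dye of each channel were taken from the labels. At early and late log KO carried Cy3 and wild type Cy5, and at mid log and early stationary phase the reverse, alike in both cultures. The submitters describe a biological duplicate, and the letters R and L are not defined further. Each letter covers KO and wild type RNA, so culture R and culture L here name replicate sets and not single cultures. The p-values measure the spread between these sets and arrays.

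Mean spot intensities were corrected with normexp (offset 50) against the median background and normalised within arrays by loess on the gene spots, in limma 3.58.1 under R 4.3.3. Spots named as missing or doublet, buffer spots and the YIR control spots were left out of the tests. The value of a gene was the median over its spots, which number 2 for 2888 genes and more for 28. A gene was kept if a spot was not marked empty in 1 channel or more on at least 2 arrays, which left out 239 of the 2916. lmFit and eBayes were run on all 16 arrays with 7 contrasts between the 8 combinations of genotype and stage and a dye term (8 residual degrees of freedom), and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 within a comparison. There were 11 contrasts and 1 F test, with no adjustment across them. The dye term called 0 genes (64 at an unadjusted p under 0.05 as labelled, and 300 with 1 culture turned). An RNA whose spots were all marked empty on every array of a group has only a bound there: the fold is then given as at least the bright group's mean over the higher of the dim spot's own value and the lowest signal not marked empty on that array, per channel after loess and Aquantile. Such a bound holds for this processing only.

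Because the cultures gave opposite KO-against-wild-type ratios under the same dyes, KO minus wild type is reported as labelled and again with the channel labels of 1 culture exchanged on its 4 KO-against-wild-type arrays. With that exchange the cultures form dye swaps, so dye effects cancel in each stage. Values by the labels of L come from turning R. The values of the KO stages are the same in both fits and their spread differs; they are given as labelled.

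The fit was tested on simulated log ratios of the 2677 genes, with the dye term and the residual SDs of the fit with R turned, and 200 genes changed per kind of effect. With consistent arrays, 88.1% of the genes changed by 1 on the log2 scale and all those changed by 2 or 3 were recovered for the average, and 9 of 201 calls were unchanged genes. For early log the recovered shares were 26.9%, 83.6% and 100% for changes of 1, 2 and 3, and for KO early stationary against early log 53.7%, 97.0% and 100%. The KO stage results are given from the fit as labelled, which was not simulated in this way and had a larger spread. For KO early stationary against early log, its median SE was 0.40 on the log2 scale, against 0.31 with R turned. The recovered shares for KO stages therefore do not carry over to the results given. When the labels of R were made wrong in the simulation, 0 genes were called for the average. This follows from the setting, as the same change was put into both cultures and then cancels. The simulated noise was independent between arrays, so the recovered shares hold for that setting only.

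The genes to be named were fixed before the data were examined by size among called genes with the same sign on all 8 KO-against-wild-type arrays (average) or in both cultures (other comparisons), and the smallest adjusted p for the differences between stages. As the files do not pair tags with names, this was shortened to at most 2 per direction. For KO minus wild type the rule was applied with R turned, a setting chosen after the data were seen. The genes for the change of the difference between stages were picked by size instead, after the data were seen. Runs of locus tags were also looked at only after the data were seen: a run is at least 4 tested tags, in the order of their numbers, all called in 1 direction. The 25 gene lists fixed beforehand are rules on gene names, products or remembered tags; none could be tied to the tags through a table, and they were not tested. A search for CcpA operator sites was not run, as no genome was used here. Alternatives were no background correction, median centring, Aquantile, the authors' value table, no filter, the mean over spots, no dye term, the KO-against-wild-type or loop arrays alone, a term for the culture letter, 1 value per culture, and leaving out each array or culture. Added after the data were seen were the exchanges of labels, leaving out spots with flag 3, and the average of the 3 log stages.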

Results

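Transcript levels were compared between a ccpA knockout (KO) and the wild type of Lactiplantibacillus plantarum, a lactic acid bacterium. CcpA, the catabolite control protein A, is a transcription regulator of carbon catabolite repression in Gram-positive bacteria. Per the labels, cultures were grown in batch on a chemically defined medium to an optical density of 1 and then stressed with sodium L-lactate. Every RNA carries the lactate label, so the arrays compare genotypes and growth stages and not lactate with its absence. Samples were labelled early log, mid log, late log or early stationary, and each genotype and stage was sampled 2 times, lettered R and L. Culture R and culture L here name the sets of KO and wild type samples with that letter. The 16 RNA samples, 8 labelled KO and 8 labelled wild type, were hybridised to 16 two-colour arrays. Of these, 8 set KO against wild type at 1 stage, and 8 set KO at a stage against KO at the next, in a closed loop per culture. Each of the 8 kinds of array was present 2 times, 1 per culture.

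Each array held 6912 spots and covered 2916 locus tags, of which 2677 passed the filter on dim genes. The median gene spot lay between 1.18 and 4.15 times its background in the Cy3 channel and between 1.12 and 3.04 times in the Cy5 channel. The weakest Cy5 channel was that of the early stationary KO-against-wild-type array of culture L, where 16% of the gene spots were not marked empty. The SD of a spot's log2 ratio, from the duplicate spots of a gene, was 0.22 to 0.62, and at most 41 gene spots on an array were saturated. The small number of cultures and arrays limits the precision of every value given here. The files do not pair locus tags with gene names, and 0 of the tags were found in the reference table used, so genes are given by locus tag and at most 2 per direction are printed for a comparison. The level of the disrupted gene itself could for this reason not be picked out, and the files do not say whether a tag printed here is its own.

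The first question was which genes differ between KO and wild type, and the labels of the KO-against-wild-type arrays alone did not settle its direction. As labelled, both cultures carried the same dye on the same genotype at each stage. The deposited value table runs Cy5 over Cy3 in R and Cy3 over Cy5 in L, so its sign opposes KO over wild type at early and late log in R and at mid log and early stationary phase in L. Across the 2677 genes, which are not independent replicates, the KO over wild type log ratios of culture R correlated with those of culture L at r = -0.65 in early log, -0.72 in mid log, -0.64 in late log and -0.66 in early stationary phase. By rank the correlation was weaker, with Spearman's rho of -0.23, -0.39, -0.51 and -0.55. Between stages of the same culture, the correlations of these arrays lay between 0.35 and 0.79. The KO loop arrays of R and L correlated positively, from 0.23 for early against mid log to 0.80 for early stationary against early log. With each culture taken alone, 101 genes differed between the labelled genotypes over the 4 arrays of R, 8 higher and 93 lower in KO, and 160 over the 4 arrays of L, 139 higher and 21 lower. In these fits the 4 stages of 1 culture served as replicates, so their p-values measure the spread between stages and not between cultures. The 90 genes called in both cultures all had opposite signs.

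**Figure D1:**
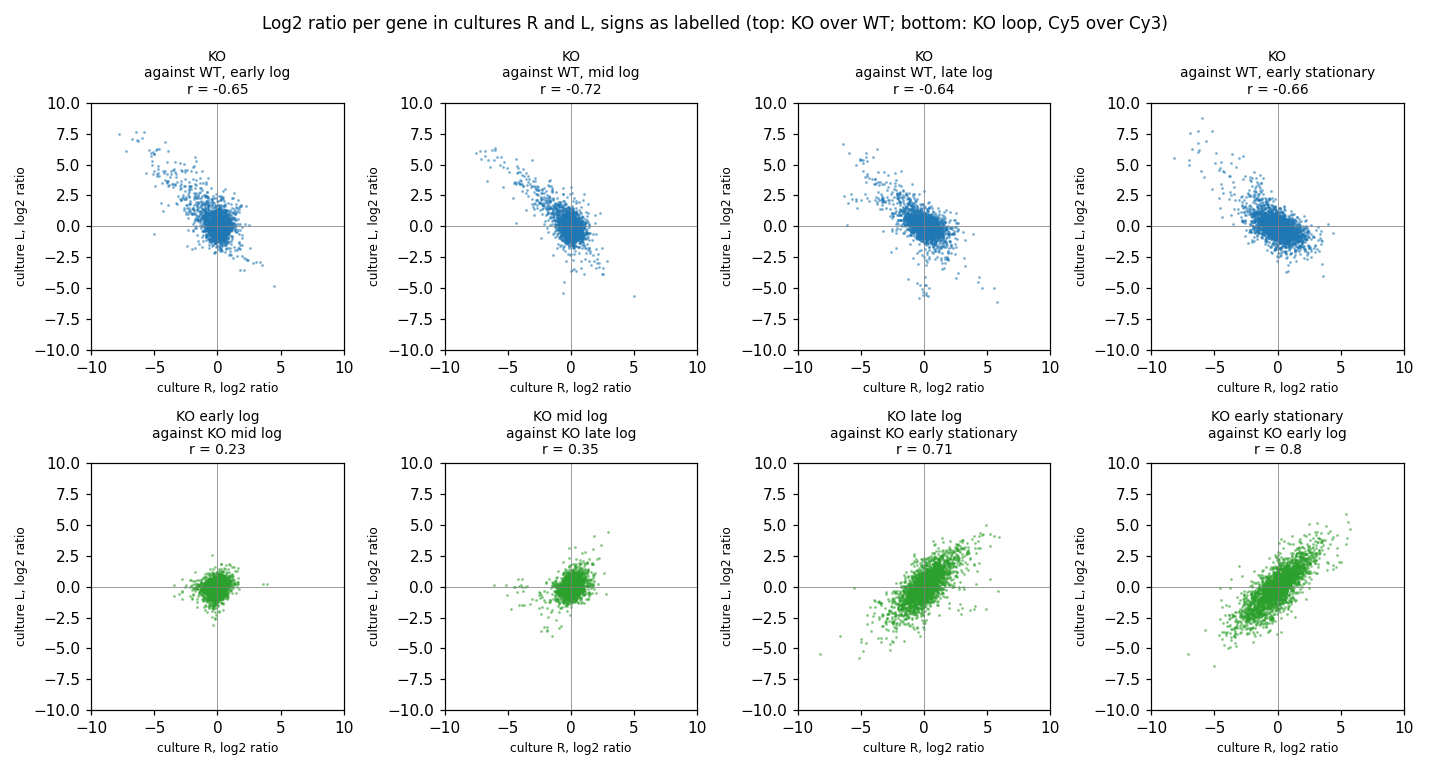
Each point is 1 of the 2677 genes, with its log2 ratio in culture R on the x axis and in culture L on the y axis, signs as labelled. The KO-against-wild-type arrays (top) slope downwards, with r from -0.72 to -0.64, and the KO loop arrays (bottom) slope upwards, with r from 0.23 to 0.80.

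With the channels as labelled, limma called 0 genes for the KO minus wild type average over the 4 stages (59 at an unadjusted p under 0.05). It also called 0 genes at early log, mid log, late log and early stationary phase (27, 17, 29 and 67 at an unadjusted p under 0.05) and 0 for a difference between stages (13 at an unadjusted p under 0.05). With the KO-against-wild-type arrays of 1 culture turned, by exchanging their channel labels, the same fit called 682 genes for the average. This setting was chosen after the data were seen. Turning culture R gives signs by the labels of culture L, and turning culture L gives each KO minus wild type value with the opposite sign. The KO minus wild type signs that follow are those by the labels of culture L. By the labels of culture R, every "higher" among them reads "lower" and the reverse, and the labels of these arrays do not decide between the readings. For the 100 genes with the largest ratios in the other culture, the KO level on the loop arrays lay nearer the channel labelled wild type for 76 to 88 genes per stage in R and for 3 to 7 in L. If the loop arrays hold KO in both channels, as labelled, these genes argue for the labels of L and against those of R.

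Over the 4 stages, 406 genes were higher and 276 lower in KO by the labels of L, and 276 higher and 406 lower by the labels of R. The larger of the groups also held the larger differences. Of the 406 genes, 229 differed at least 2-fold and 49 at least 8-fold, against 48 and 1 of the 276. The 8 arrays behind each average are the 4 stages of 2 cultures, so n = 8 does not count independent replicates. The SEs and p-values treat these arrays as independent. The largest fitted log2 difference was that of lp_0181, at 6.37 ± 0.25 (SE, n = 8 arrays, adjusted p = 2.5e-11). Its means were 6.59 in R and 6.16 in L, and it was the end of a run of 10 tested locus tags in a row that all passed the threshold on the same side, with a mean of 5.05. Close to it lay lp_3548, at 6.33 ± 0.28 (SE, n = 8, adjusted p = 1.1e-10), in a run of 9 tags with a mean of 2.55. In the opposite direction lay lp_3579, at -3.64 ± 0.36 (SE, n = 8, adjusted p = 1.4e-06), in a run of 6 tags with a mean of -1.60, and lp_2256, at -2.49 ± 0.21 (SE, n = 8, adjusted p = 2e-07). The files do not tell whether lp_2256 or another of these 4 tags belongs to the disrupted gene, whose level would bear on the direction. With R turned, each of these 4 genes lay on the same side on 8 of 8 arrays, which the rule for naming genes required. As labelled, the 4 arrays of R lay on the other side from the 4 of L for each of them. In the dimmer channel, all spots of lp_0181 were marked empty on 5 of the 8 arrays, of lp_3548 on 6 and of lp_2256 on 4, so the sizes of these differences are limited by the dimmest signal measured. For lp_3579, a spot was saturated on 1 of the 8 arrays in the brighter channel. At mid log, with such spots on both arrays, lp_0181 is given as at least 55.2-fold. The number of calls was 160 without culture R and 101 without culture L, where 4 arrays remained, and 449 without the early log array of L. With median centring in place of loess, 377 genes were higher and 408 lower by the labels of L.

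Genes that differed between KO and wild type lay side by side in the numbering of the locus tags. For the average, 35 runs of at least 4 tested tags in a row were called in 1 direction, 29 on the side of lp_0181 and 6 on the other. They held 204 of the 682 called genes, or 29.9%, and the longest spanned 12 genes. In 10000 shuffles of the gene order such runs held 6.1 genes on average and at most 29 (permutation p = 1e-04, the smallest these shuffles can give). At early log 17 runs held 93 of the 258 called genes, at mid log 17 runs held 95 of 237, at late log 15 runs held 108 of 334, and at early stationary phase 15 runs held 86 of 545.

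**Figure D2:**
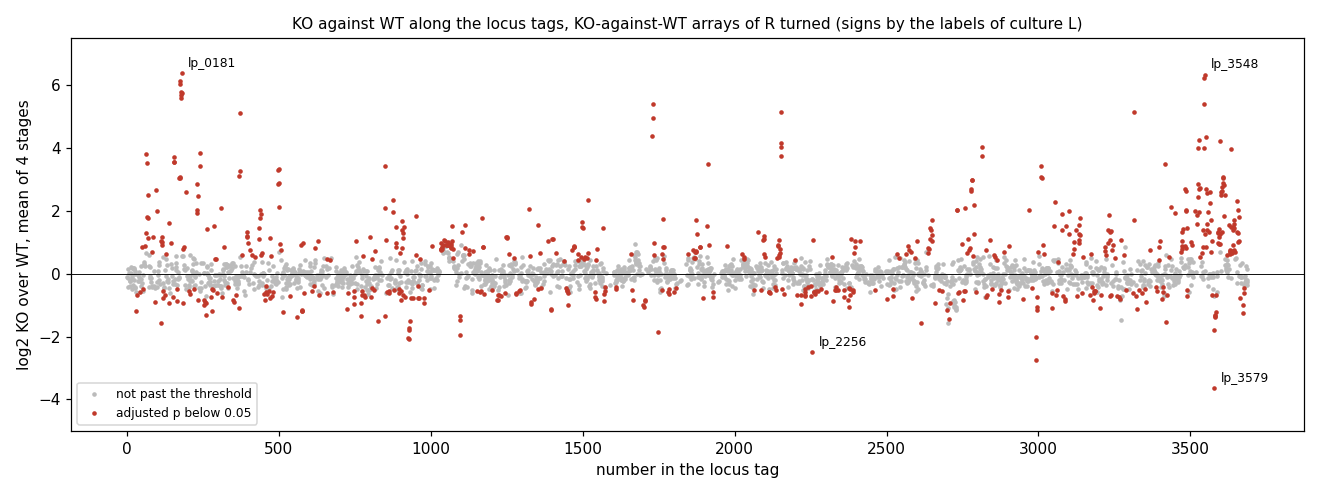
The log2 difference between KO and wild type, mean of the 4 stages, is plotted for each tested gene against the number in its locus tag, with the KO-against-wild-type arrays of R turned. Red points passed adjusted p 0.05, and the named genes lie at 6.37 (lp_0181), 6.33 (lp_3548), -2.49 (lp_2256) and -3.64 (lp_3579); the labels of R would mirror the plot about 0.

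At the single stages, the counts of called genes were one-sided in early and mid log and more balanced later. On both early stationary arrays, the channel that is KO by the labels of L was the dimmer one. Of its gene spots, 16% were not marked empty in L and 45.1% in R, against 45.8% and 64.6% in the other channel. Whether this weaker KO signal contributed to the genes lower in KO at that stage was not tested. By the labels of L, 229 genes were higher and 29 lower in KO at early log, 203 and 34 at mid log, 226 and 108 at late log, and 278 and 267 at early stationary phase; by the labels of R the pairs exchange. At early log lp_0175 had the largest fitted difference, at 7.61 ± 0.33 (SE, n = 2 arrays, limma adjusted p = 1.6e-09). It belonged to the run of 10 tags that holds lp_0181, and as its spots were marked empty on both arrays in the dimmer channel, the difference is given as at least 82.8-fold. The run of 10 tags averaged 5.56 at early log, 5.61 at mid log, 4.20 at late log and 4.83 at early stationary phase, and all 10 genes passed the threshold at each of these stages. On the other side at early log lay lp_3579, at -4.66 ± 0.71 (SE, n = 2, limma adjusted p = 0.00031). At late log, 28 tags in a row were higher by the labels of L, with a mean of 2.37 (2.94 in R and 1.78 in L), and at mid log their mean was 0.04 (0.19 in R and -0.09 in L). The cultures differed in sign for these tags at early log, at -1.16 in R and 0.94 in L, and at early stationary phase, at 1.40 in R and -0.11 in L. At early log, mid log and early stationary phase 0, 0 and 2 of the 28 were called. At early stationary phase lp_1912 stood at 7.22 ± 0.53 (SE, n = 2, limma adjusted p = 1.7e-07) with spots marked empty in the dimmer channel on 1 of the 2 arrays, which limits its size, and lp_0769 at -3.80 ± 0.33 (SE, n = 2, limma adjusted p = 1.4e-06) with spots marked empty in KO on both arrays, at least 3.37-fold. Over the alternatives, the value ran from -4.22 to -1.45 for lp_0769 at early stationary phase and from 5.41 to 9.14 for lp_0175 at early log. Their bounds therefore hold for the main processing only. In total 90 genes were called on the side of lp_0181 at all 4 stages and 3 on the other side.

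Leaving out 1 array of a stage left 1 array there, which is assumed to vary like the others. Calls then fell to 117 at early log (without L), 154 (without R) and 110 (without L) at mid log, 140 (without R) and 207 (without L) at late log, and 224 (without R) and 345 (without L) at early stationary phase. At early stationary phase the split also moved with the scaling, to 219 higher and 565 lower with median centring, by the labels of L.

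The difference between KO and wild type itself changed with the stage of growth for 194 genes (limma moderated F test). Set against early log, 169 genes had another difference at early stationary phase, 44 higher and 125 lower by the labels of L and the reverse by those of R. The dimmer channel of the early stationary arrays, which is KO by the labels of L, may bear on this split, which was not tested. The run of 6 tags with lp_3579 had a mean KO minus wild type difference of -2.74 at early log, -3.01 at mid log, -0.79 at late log (-0.13 in R and -1.22 in L) and 0.17 at early stationary phase (0.20 in R and -0.11 in L), and 4 of its 6 genes were called for the change between early log and early stationary phase. For single genes the change of the difference was largest at lp_1729, at -5.56 ± 0.56 on the log2 scale (SE, n = 2 arrays per stage, limma adjusted p = 0.00012; -3.92 in R and -5.97 in L), and in the other direction at lp_1912, at 4.5 ± 0.74 (SE, limma adjusted p = 0.0024; 5.37 in R and 4.07 in L). The size for lp_1912 is limited by the empty spots named above. Over the alternatives this change ran from -6.41 to -2.75 for lp_1729 and from 3.31 to 5.68 for lp_1912. The count of 169 was 63 without the early log array of R, 58 without that of L and 105 without the early stationary array of R, and it was 318, of which 29 higher, with median centring. The count of 194 was 104 without the late log array of R and 122 without the early stationary array of R.

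**Figure D3:**
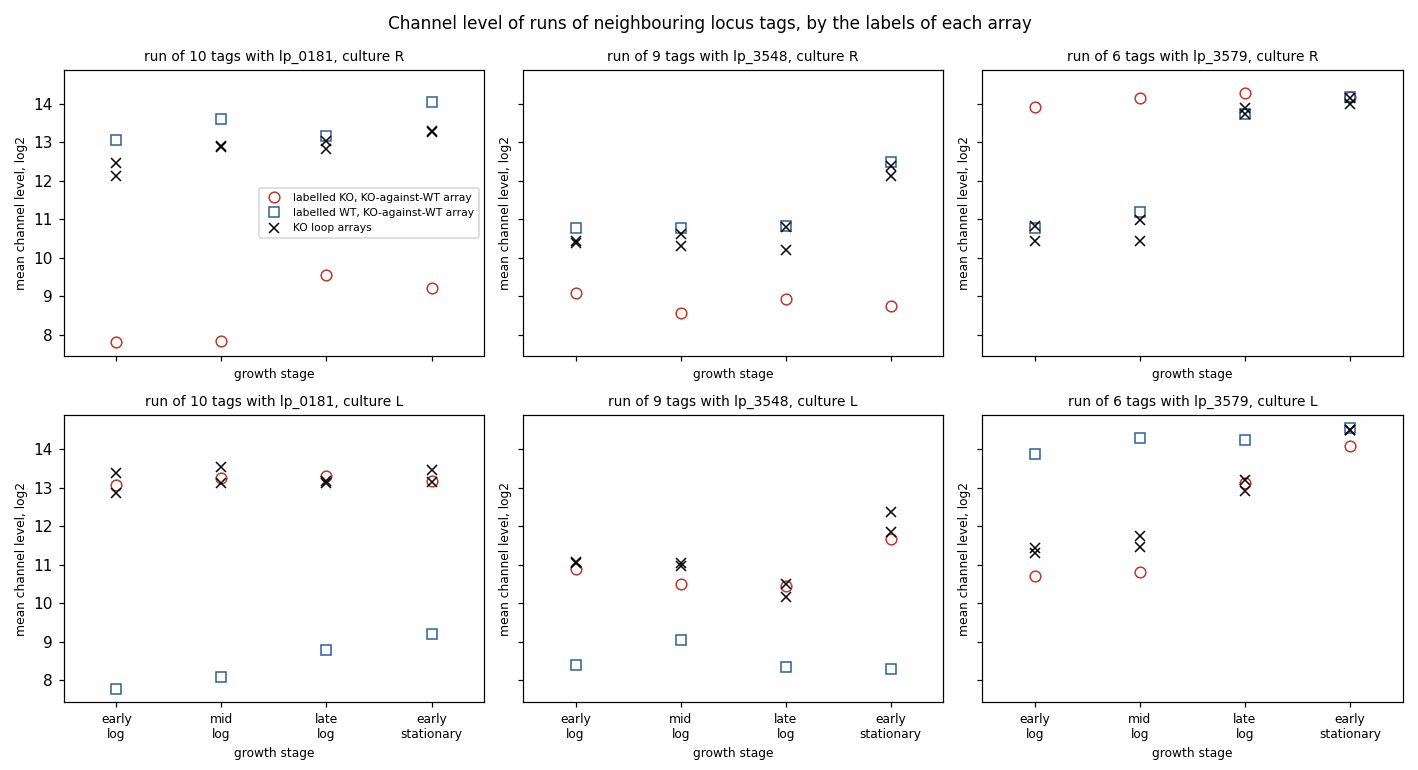
Mean log2 level per channel of the runs of 10, 9 and 6 neighbouring locus tags that hold lp_0181, lp_3548 and lp_3579, by growth stage, in culture R (top) and L (bottom). Circles and squares are the channels labelled KO and wild type on the KO-against-wild-type arrays, and crosses are the KO channels of the loop arrays. The crosses lie with the squares in R and with the circles in L, except for the run with lp_3579 at early stationary phase. There the circle and the square nearly coincide in R (14.17 and 14.16). In L the crosses (14.50) lie nearer the square (14.54) than the circle (14.08).

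The second question was how the KO changed along growth, for which the loop arrays of both cultures ran the same way. Each KO stage had 1 RNA sample per culture, and each sample was put on several arrays, which the fit treated as independent. The large change came with the early stationary phase. The early stationary channel was the dimmer one on each loop array that held it. Against late log, 22.2% of its gene spots were not marked empty in R and 26.7% in L, and 65.8% and 56.9% of those of late log. Against early log, the shares were 45% in R and 41.2% in L, and 49.6% and 77.2% for early log. How far this weaker signal shaped the counts was not tested. Between early log and early stationary phase, limma called 869 genes in KO, 406 higher and 463 lower in early stationary phase, and between late log and early stationary phase 600, 265 higher and 335 lower. Between mid log and early log it called 0 genes (40 at an unadjusted p under 0.05), and between late log and mid log 1 gene, lp_3665, which lay 1.80 lower at late log (SE 0.24, adjusted p = 0.039). This single call was lost in 14 of the 16 fits without 1 array. The largest rise from early log to early stationary phase was that of lp_0266, 5.56 ± 0.57 on the log2 scale (SE, adjusted p = 0.00024; 5.15 in R and 5.97 in L), followed by lp_3359 at 4.96 ± 0.58 (SE, adjusted p = 0.00034), whose spots were marked empty on 2 of 4 early log loop channels. The largest fitted falls were those of lp_3421, at -5.85 ± 0.77 (SE, adjusted p = 0.00053), with spots marked empty on 3 of 4 early stationary loop channels and a saturated spot on 2 of 4 early log ones, and lp_3397, at -4.37 ± 0.35 (SE, adjusted p = 0.00013), whose spots were marked empty on all 4 early stationary loop channels, a fall of at least 9.26-fold. Runs of neighbouring tags were seen here too, as 48 runs, 20 rising and 28 falling, held 235 of the 869 genes, against 13.1 on average and at most 59 in the 10000 shuffles (permutation p = 1e-04, the smallest they can give).

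Between late log and early stationary phase, 5 tags in a row that include lp_0262 rose by a mean of 4.84 on the log2 scale, 5.87 in R and 3.81 in L. For lp_0262 the change was 6.50 ± 1.90 (SE, adjusted p = 0.032), at least 43.9-fold as its spots were marked empty on all 4 late log loop channels, and its call was lost without any 1 of 7 of the 8 loop arrays, with adjusted p from 0.051 to 0.21. The fall of lp_3421, at -4.88 ± 0.77 (SE, adjusted p = 0.0022), was kept in each of those fits, and its size is limited by the same empty spots and by a saturated spot on 1 of 4 late log loop channels. The 28 tags that stood apart at late log had a mean of -2.57 between late log and early stationary phase in KO, and 16 of them passed the threshold, all lower.

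The counts, SEs and p-values for KO stages, those of lp_0262 included, rest on a spread that includes the conflict between the cultures on the other arrays. With the KO loop arrays alone, the counts were 1346 for early stationary against early log, 1059 for early stationary against late log and 20 for late against mid log, and they were 1390, 1106 and 46 with either culture's KO-against-wild-type arrays turned. Without the early stationary against early log array of R or L the count of 869 was 450 or 404, and without the late log against early stationary array of R or L the count of 600 was 257 or 196. With median centring, 259 genes were higher and 555 lower in early stationary phase than in late log, and without background correction 191 and 155.

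**Figure D4:**
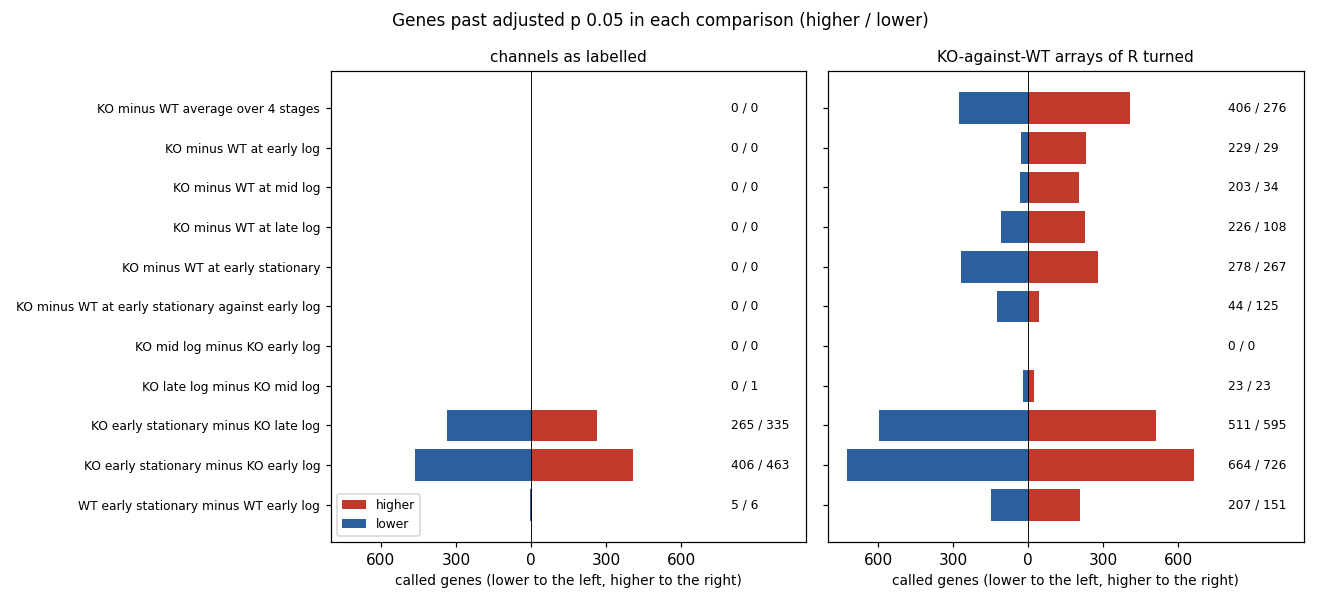
Number of genes past adjusted p 0.05 in each comparison, higher to the right and lower to the left, with the channels as labelled (left) and with the KO-against-wild-type arrays of R turned (right). The KO minus wild type bars are empty as labelled and reach 406 higher and 276 lower for the average when turned; turning L in place of R exchanges higher and lower in the first 6 rows.

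For the wild type, no 2 of its RNA samples shared an array, and the change from early log to early stationary phase follows only indirectly, through the KO loop. As labelled, 11 genes were called, 5 higher and 6 lower in early stationary phase. The count was 358 (207 higher and 151 lower) with the KO-against-wild-type arrays of R turned and 1012 (441 higher and 571 lower) with those of L turned. Turning L calls wild type the channel that lay nearer the KO loop level of L for at least 93 of the 100 genes, and turning R does so for at most 24 in R. As labelled, the count was 0 or 1 in 13 of the 16 fits without 1 array, 48 without the late log array of R or of L, and 378 without the early stationary KO-against-wild-type array of L. With median centring it was 30, of which 17 higher and 13 lower.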

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

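The matching of loop arrays to channels, the turned fits and the checks on choice of genes and saturation were chosen only after the results were seen; the test of weaker signal and the splits with R turned were fixed before their results.

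As labelled, 343 genes lay on one side of 0 on all 4 KO-against-wild-type arrays of culture R and on the other side on all 4 of culture L (106 higher and 237 lower in R), while 3 were higher and 4 lower on all 8; this difference between the cultures was not tested gene by gene. A candidate explanation is an exchange of the channel labels on the arrays of R. For the 100 genes with the largest ratios in the other culture, the level in the KO loop channels of R lay nearer the channel labelled wild type for 76 to 88 genes at every stage, so the lowest of these counts was 76. The same exchange on the arrays of L is argued against, since at most 7 of 100 genes had a KO loop level in L nearer the channel labelled wild type. An exchange of strains in all RNA of 1 culture is argued against by the loops, whose levels in R and L differed by a median of at most 0.74 on the log2 scale at these genes, while the 2 channels of a KO-against-wild-type array lay far apart. Open and untested is whether the strain in all loops is the one its label names, and so which strain had the higher levels.

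With the arrays of 1 culture turned, 194 genes had a KO minus wild type difference that varied with the stage, and 169 differed between early stationary phase and early log, each by the test of the difference itself. For the 50 genes highest in KO at early and mid log by the labels of L, chosen in 1 culture and measured in the other, the median difference went from 4.42 at early log to 2.68 at early stationary phase in R and from 4.49 to 3.08 in L, and for the 50 lowest from -0.83 to -0.75 in R and from -1.50 to -0.25 in L. For the highest genes, regression to the mean from noise of the choosing culture is argued against by this measure, as the larger of the remaining shares was 68.6%. Saturated spots are argued against by 73.7% without the genes that had one. As the genes were chosen at the log stages, a smaller difference at a later stage can also follow from that choice of stage, which this measure cannot exclude. Weaker signal in early stationary phase may contribute and cannot be told apart from a change in the cells: genes chosen at that stage reached 85.2% (R) and 86.5% (L) of the size that genes chosen at early log had there, between the bounds set beforehand. Growth stage, which the design names, stays open as the biological explanation.

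For the KO minus wild type average with R turned, 1 of 100 splits drawn from the 128 ways to exchange the channels of the 8 arrays gave as many called genes, the real value being 682 and the highest of the others 356. As R was turned because the cultures ran opposite ways on the same arrays, this count does not exclude chance. As labelled, the real value was 0, so all 100 splits reach it by construction, which tests nothing. The highest of the others, 682, equals the count with 1 culture turned. That exchange is itself 1 of the 128 ways, so this count adds no support.

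Among spots outside the tests, 19.2% of those named missing, 21.9% of those named doublet and 15.9% of the YIR control spots were not marked empty, against 11.9% of the buffer spots.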

How the results depend on the processing

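The exchanges of labels, leaving out flag 3 spots and the average of the 3 log stages were chosen after the data were seen. Alternatives that moved a count of called genes by over 1.5 times are listed here, and the cause was not tested unless stated. From 0 as labelled, turning the KO-against-wild-type arrays of either R or L gave 682 genes for the average, 258 at early log, 237 at mid log, 334 at late log, 545 at early stationary phase, 169 for early stationary phase against early log and 194 for a difference between stages. Turning all 8 arrays of L, the direction of the authors' value table, gave 239, 94, 83, 47 and 53 for the average and the stages, and 0 for each KO stage comparison and for the wild type, as the loops then oppose each other. As labelled, leaving out 1 array or culture gave 0 to 160 for the average (101 without L), 0 to 16 at late log, 0 to 21 at early stationary phase and 0 to 7 for a difference between stages.

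For KO early stationary against early log (869), the loop arrays alone gave 1346, either turning 1390, and leaving out an array 404 to 1019. For KO early stationary against late log (600), no background correction gave 346, leaving out flag 3 spots 267, the loop arrays alone 1059, either turning 1106, and leaving out an array 196 to 760. For KO late against mid log (1), median centring, the authors' value table and leaving out flag 3 spots gave 0, the loop arrays alone 20, either turning 46, and leaving out an array 0 to 1. For the wild type (11), no background correction gave 19, median centring 30, the authors' values 47, leaving out flag 3 spots 0, no dye term 127, turning R 358, turning L 1012, and leaving out an array 0 to 378.

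With R turned, leaving out an array or culture gave 101 to 703 for the average (682), 117 to 267 at early log (258), 110 to 244 at mid log (237), 140 to 348 at late log (334), 224 to 575 at early stationary phase (545), 58 to 175 for early stationary phase against early log (169) and 104 to 217 for a difference between stages (194). Leaving out flag 3 spots gave 451 for the average, 102 for early stationary phase against early log and 98 for a difference between stages. The authors' value table gave 160 at late log and 69 for a difference between stages. No background correction gave 355 at early stationary phase. The KO-against-wild-type arrays alone gave 358 at early stationary phase, 71 against early log and 85 for a difference between stages. Median centring gave 318 for early stationary phase against early log and 327 for a difference between stages. The average of the 3 log stages alone called 529.

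The culture letter as a replicate block kept 0 calls as labelled and gave 700 for the average with R turned (682 without); it was fitted for the average and the 4 single stages only, and moved none of these counts by over 1.5 times. With 1 value per culture, 0 and 628 genes were called. For the 33 values of named genes, 822 of 860 alternatives kept direction and call, 38 lost the call and 0 reversed, label exchanges aside. Not run were the scanner's own log ratio and a dye term per slide, which the files used here do not give, the gene lists and the operator search. Low signal over background limits the early stationary arrays most.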

Other observations

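The values by position in the tag numbering and the sets of genes were chosen after the data were seen, and the test of printing position before its result. The genes that differed between KO and wild type were not spread evenly over the numbering. At tag numbers of 3400 and above, 96 of 232 tested genes, or 41.4%, were higher in KO over the 4 stages by the labels of L (lower by those of R), 71 of them at least 2-fold, against 310 of 2445, or 12.7%, below 3400. The share on the opposite side was 8.62% there and 10.5% below. The first 200 tag numbers followed, with 36 of 149 genes, or 24.2%. The bound of 3400 was set after the values were seen, and the excess was not tested.

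The 28 tags in a row that were higher in KO at late log by the labels of L fell towards early stationary phase in KO, by a mean of 2.57 on the log2 scale, with 16 of the 28 called. From early log to early stationary phase their mean change was -2.04 in KO (11 called), and in the wild type -2.77 with R turned (14 called) and -1.31 with L turned (3 called). In the loops their mean change between mid and late log was -0.05, with 0 of the 28 called. For the 50 genes chosen in the other culture as highest in KO in the log phase by the labels of L, the median change of KO from early log to early stationary phase was 0.00 in R and -0.02 in L, and the median change of their KO minus wild type difference was -1.48 and -1.58. For the 50 chosen as lowest these medians were 0.77 in R and 0.85 in L for KO, and 0.20 and 0.89 for the difference.

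Genes with consecutive locus tags had related ratios, with a correlation of 0.59 over 2489 pairs of neighbours in the numbering, 1 culture turned. Printing position on the array is argued against: over 981 pairs of genes printed next to each other with tags over 50 apart, the correlation was -0.01. A hypothesis is that neighbours are transcribed together, which may be tested with a genome annotation; cross-hybridisation between similar neighbouring genes was not tested.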
